A study of Mus musculus with 35 samples.

How the data were processed

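Liver RNA of 35 mouse samples in 14 groups was hybridised to Affymetrix whole-genome mouse arrays, 1 sample per array, 3 arrays for each untreated and PH group and 1 or 2 for each sham group. Per the labels, RNA was isolated with RNeasy columns and 5 µg was labelled. The deposited values are RMA signals on the log2 scale, made by the authors and held for 45101 probe sets, 64 of them controls. RMA corrects background, equalises the distribution of probe signals between arrays and summarises the probes of a set. Its version and the arrays normalized together are not given in the sources used here. Arrays have no read depth.

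Probe sets were assigned to genes by the platform table, which lists 35890 of them, 34945 with 1 gene symbol and 932 with several. For each of 18193 genes the probe set with the highest mean over all arrays was used, among those with 1 symbol. This concerned 9010 genes with over 1 probe set. The 9160 unlisted probe sets and those with several symbols were left out of the tests per gene. No genome build is named in the files, and no positions are given.

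Group means were fitted to all 35 arrays with limma 3.58.1 in R 4.3.3, with residual variances moderated by eBayes (21 residual and 3.29 prior degrees of freedom). In 23 contrasts PH was compared with the sham of the same age and time and with 0 h, sham with 0 h as a mean over times, old with young, and the PH response of old with that of young. The Benjamini-Hochberg threshold was an adjusted p of 0.05 per contrast. The moderated test covers groups of 1 to 3 arrays, and a group with 1 array is assumed to vary like the others.

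A set of 38 gene lists was tested in each contrast on the measured members with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. Of 874 list tests 312 passed with the preset correlation and 10 also with the estimated one. Counts over a list alone use p-values adjusted within it. List scores are the mean log2 level of the members relative to the 0 h arrays of the same age, and ages were compared by two-sided exact permutation tests. Named genes were chosen by a rule, with a panel of 25 (Ccnb1 is not measured). Each list described gave up to 4 members with the largest changes past the threshold, or else the 2 with the highest mean level. A contrast gave the 5 largest rises and 5 largest falls past the threshold whose arrays do not overlap between groups. Overlap was not required with under 5 such genes (falls of old against young over all conditions) or in the age difference of the response. Chance separates 10% of genes for 3 against 3 arrays, and more for the fewer arrays of PH against sham. In other contrasts panel genes not passing are given as a range.

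The groups, contrasts, lists, the rule for named genes and the alternatives were chosen before the data were examined, except for leaving out 2 outlying arrays. The alternatives changed the probe set of a gene, the unit of the test, a filter on dim genes, the scaling, the variance prior, array weights, the arrays in the fit, a block for the replicate number, the control group and each array in turn. The single young 38 h sham array was never left out, as its group would be empty. In simulated young PH against sham, 94% of 2-fold shifts were recovered at 24 h and 77.6% at 38 h. Measured Igfbp1 (4.13-fold) did not pass at 24 h, so not passing does not exclude 2-fold changes. Figures used matplotlib 3.10.9 in Python 3.11.15.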

Results

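Gene expression was measured in livers of male CB6F1 mice on 35 arrays, 1 sample per array. Young mice (5 to 6 months) came from 1 supplier and old mice (25 to 27 months) from another, so age and supplier cannot be separated. Livers were taken untreated (0 h, 3 arrays per age), after 70% partial hepatectomy (PH) at 24, 38 and 48 h (3 arrays per age and time), or after sham surgery at the same times (young 2, 1 and 2 arrays, old 2, 2 and 2). The labels do not say that replicates are separate animals, so p-values measure the spread between samples. It is pooled per gene over all 35 arrays, not taken from the groups compared. Changes are log2 differences ± the standard error of the limma fit, and "rose" or "fell" marks an adjusted p under 0.05 over 18193 genes. The number of arrays limits the precision, and arrays correlated with each other at r from 0.922 to 0.997 across genes.

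In young livers the S phase score, the mean log2 level of 32 replication genes above the 0 h livers, was 0.94 ± 0.36 (SD, n = 3) at 24 h after PH, 2.04 ± 0.23 at 38 h and 1.46 ± 0.13 at 48 h. In old livers it was -0.02 ± 0.23, 0.83 ± 0.75 and 1.13 ± 0.29 at the same times. The score of 34 mitotic genes was 0.62 ± 0.25, 2.37 ± 0.60 and 3.21 ± 0.24 in young livers and 0.00 ± 0.12, 1.04 ± 1.04 (arrays 2.15, 0.88 and 0.09) and 2.97 ± 0.17 in old livers. Sham livers of both ages stayed between -0.28 and 0.25 on both scores. By a two-sided exact permutation test, old and young PH livers differed in the S phase score with p = 0.1 at 24 h and at 38 h, the smallest value 3 against 3 arrays can give, and p = 0.3 at 48 h (adjusted over 114 tests 0.285, 0.285 and 0.561). For the mitosis score p was 0.1, 0.3 and 0.3 (adjusted 0.285, 0.561 and 0.561).

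**Figure D1:**
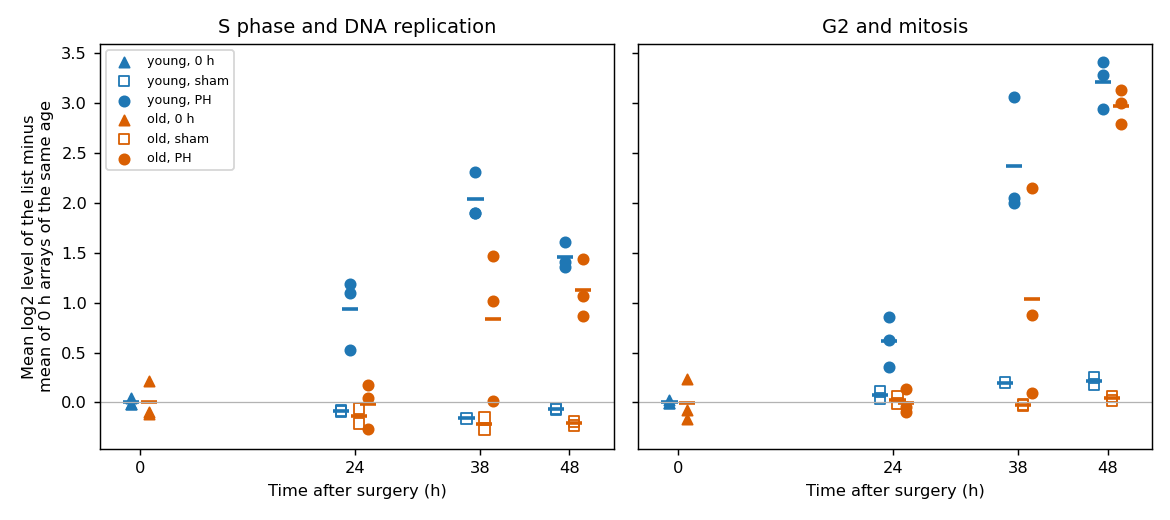
Mean log2 level of the S phase list (left) and the mitosis list (right) per array, relative to the 0 h arrays of the same age, against time after surgery in hours. Symbols are single arrays of young (blue) and old (orange) mice and bars are group means, and the S phase means at 38 h after PH are 2.04 in young and 0.83 in old livers.

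PH was compared with sham surgery of the same age and time to ask which genes respond to loss of liver mass beyond the operation itself. At 24 h in young livers genes of DNA replication rose. Rrm2, a subunit of ribonucleotide reductase, rose by 3.31 ± 0.60, and Mcm5 (2.56 ± 0.62), Mcm6 (2.52 ± 0.58) and Mcm4 (1.97 ± 0.37), subunits of the replicative helicase, rose with it, as did the replication clamp Pcna (1.35 ± 0.26). In the S phase list, 9 of 32 members rose (21 over the list alone). A median of 1.02 gave camera adjusted p = 6.31e-21, and 0.154 with an estimated correlation. In the mitosis list 0 of 34 members passed in limma (1 over the list alone, 5 at an unadjusted p under 0.05). A median of 0.46 gave camera adjusted p = 8.32e-05, and 0.611 with an estimated correlation. Cdk1 was at 1.30 ± 0.50 and Mki67, a proliferation marker, at 1.13 ± 0.66, without passing, and neither did cyclin D1 (Ccnd1, 1.75 ± 0.54) or the CDK inhibitor Cdkn1a (1.67 ± 0.46). Genes of cholesterol synthesis were lower as a set: 1 of 20 members fell (18 over the list alone), the sterol reductase gene Tm7sf2 among them (-0.71 ± 0.13). A median of -1.53 gave camera adjusted p = 1.91e-15, and 0.258 with an estimated correlation.

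Among nucleolar genes of ribosome biogenesis, 3 of 24 members rose (8 over the list alone), including Rrs1 (1.08 ± 0.14), Nolc1 (0.77 ± 0.18) and Nop56 (0.64 ± 0.15). A median of 0.35 gave camera adjusted p = 8.96e-10, and 0.286 with an estimated correlation. In the heat shock list 1 of 14 members rose (6 over the list alone), the mitochondrial co-chaperonin gene Hspe1 (0.60 ± 0.12). A median of 0.64 gave camera adjusted p = 2.29e-09, and 0.127 with an estimated correlation. Against 0 h these lists scored -0.01 and -0.1 after PH and -0.42 and -0.84 after sham. The transcription factor gene Cebpb rose by 0.91 ± 0.14, while Cebpa (-0.63 ± 0.19) did not pass. Thrombomodulin (Thbd, 3.25 ± 0.57) and the fatty acid binding protein gene Fabp4 (3.16 ± 0.73) rose. Fabp4 was the 1 of 8 adipose genes that rose, and the adipose score against 0 h was 0.53 ± 0.59 (SD, highest array 1.22) after PH and -0.09 after sham. Cnmd (-1.41 ± 0.30), 1810008I18Rik (-1.30 ± 0.25) and the interferon-induced GTPase Iigp1 (-1.05 ± 0.22) fell. Bbip1 (-0.99 ± 0.14) and D130043K22Rik (-0.88 ± 0.20) fell at 24 h in young livers. Ccne1 (0.30 ± 0.22), Ccna2 (0.67 ± 0.40), Foxm1 (0.18 ± 0.14), Top2a (1.23 ± 0.57), Smarca2 (0.24 ± 0.40) and Hnf4a (-0.01 ± 0.09) did not pass. Alb (0.00 ± 0.05), Afp (0.44 ± 0.23), Igfbp1 (2.04 ± 0.71), Cyp7a1 (0.49 ± 0.72), Saa2 (-0.13 ± 0.57) and Lcn2 (0.07 ± 0.51) did not pass. Arntl (0.37 ± 0.40), Dbp (-0.93 ± 0.78), Igf1 (0.19 ± 0.08) and Cdc20 (0.45 ± 0.45) did not pass. limma called 129 genes (107 higher and 22 lower), against 86 higher and 33 lower with arrays centred on their medians and 86 higher and 49 lower with quantile normalization repeated. The count was 1 without young sham 24 h replicate 1, 13 without young sham 24 h replicate 2, 10 without young PH 24 h replicate 1 and 39 without young PH 24 h replicate 2, but 897 in a fit on the 5 arrays compared, 713 without the 2 old PH arrays that stand apart and 1121 with the shams of an age pooled. 18 of the 18 genes named as passing lost it with 1 array left out, most often without young sham 24 h replicate 1 (18).

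By 38 h in young livers both replication and mitosis genes had risen. Rrm2 rose by 5.61 ± 0.76, Mcm6 by 4.20 ± 0.73, Mcm5 by 4.07 ± 0.78 and cyclin E2 (Ccne2) by 3.76 ± 0.50. In the S phase list, 28 of 32 members rose (28 over the list alone). A median of 2.31 gave camera adjusted p = 1.32e-35, and 0.0493 with an estimated correlation. Survivin (Birc5, 4.76 ± 0.92), Mki67 (4.18 ± 0.84), topoisomerase II alpha (Top2a, 3.81 ± 0.73) and the cytokinesis regulator Ect2 (3.72 ± 0.61) led the mitosis list, in which 27 of 34 members rose (30 over the list alone). A median of 2.22 gave camera adjusted p = 4.24e-27, and 0.134 with an estimated correlation. Cyclin D1 (2.75 ± 0.68), Cdkn1a (2.74 ± 0.58), the retinoblastoma-like gene Rbl1 (3.07 ± 0.56) and the CDK inhibitor Cdkn2c (2.38 ± 0.54) rose in the list of G1 regulators, where 10 of 20 members rose (12 over the list alone). A median of 0.75 gave camera adjusted p = 3.37e-08, and 0.00524 with an estimated correlation.

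Early response genes rose against sham at 38 h in young livers, among them Egr1 (4.10 ± 0.91), Fos (3.18 ± 0.71) and Junb (1.45 ± 0.40), and 5 of 17 members rose (6 over the list alone). A median of 1.15 gave camera adjusted p = 2.17e-05, and 0.352 with an estimated correlation. Against 0 h the mean score of this list was 0.22 ± 0.61 (SD, n = 3, lowest array -0.48) after PH and -1.05 in the sham array. The hepatic insulin-like growth factor binding protein gene Igfbp1 rose by 4.28 ± 0.90, and Cebpb by 1.03 ± 0.17, but they were at 0.46 and 0.22 against 0 h without passing, and Cebpa fell (-0.87 ± 0.24). Bile acid genes fell, led by the sterol 12-hydroxylase gene Cyp8b1 (-3.75 ± 0.86): 3 of 20 members fell (5 over the list alone). A median of -0.46 gave camera adjusted p = 0.0414, and 0.766 with an estimated correlation. Albumin (-0.02 ± 0.06) and Hnf4a (-0.02 ± 0.11) did not pass. Stellate cell and matrix markers moved with these groups, with Col4a1 (2.48 ± 0.56) and Sparc (1.31 ± 0.33) up. A median of 0.67 gave camera adjusted p = 0.00397, and 0.766 with an estimated correlation. Dmbt1 (-5.42 ± 1.16), the taurine synthesis gene Csad (-2.55 ± 0.61) and Arrdc3 (-2.31 ± 0.54) fell, and the cohesin acetyltransferase gene Esco2 (4.67 ± 0.75) rose. Gm6958 (4.51 ± 0.92) and D17H6S56E-5 (4.34 ± 0.77) rose at 38 h in young livers. Gm2788 (-2.67 ± 0.76) fell. Ier2 (1.15 ± 0.26) rose in these lists. Slc27a5 (-0.85 ± 0.21) and Cyp27a1 (-0.59 ± 0.16) fell in these lists. Ccne1 (0.95 ± 0.28), Ccna2 (2.32 ± 0.51), Cdk1 (3.53 ± 0.63) and Pcna (2.61 ± 0.33) rose. Foxm1 (0.46 ± 0.18), Smarca2 (0.23 ± 0.50), Afp (0.94 ± 0.29), Cyp7a1 (-2.20 ± 0.91), Saa2 (0.11 ± 0.71) and Lcn2 (1.13 ± 0.65) did not pass. Arntl (-0.55 ± 0.50), Dbp (0.96 ± 0.99) and Igf1 (0.19 ± 0.11) did not pass. limma called 1103 genes (836 higher and 267 lower), against 708 higher and 470 lower with arrays centred on their medians and 686 higher and 692 lower with quantile normalization repeated, against a single sham array that is assumed to vary like the other groups. With 1 PH array left out, 5 of the 35 genes named as passing lost it, most often without young PH 38 h replicate 2 (5), and the bile acid list did not pass without young PH 38 h replicate 1 (median -0.41) or replicate 2 (median -0.40). The single sham array could not be left out, so these counts do not cover it.

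At 48 h in young livers most measured mitotic genes had risen. Birc5 rose by 5.35 ± 0.73, the ubiquitin ligase partner Ube2c by 4.83 ± 0.63, Mki67 by 4.59 ± 0.66, Ect2 by 4.58 ± 0.48 and Cdk1 by 4.17 ± 0.50, and in the mitosis list 32 of 34 members rose (33 over the list alone). A median of 3.24 gave camera adjusted p = 8.31e-40, and 0.0619 with an estimated correlation. Rrm2 rose by 4.06 ± 0.60 and Mcm6 by 3.19 ± 0.58, and in the S phase list 27 of 32 members rose (29 higher and 1 lower over the list alone). A median of 1.47 gave camera adjusted p = 1.28e-19, and 0.192 with an estimated correlation. Targets of p53 rose as a set: 12 of 18 members rose (12 over the list alone), with Cdkn1a at 3.19 ± 0.46, the antiproliferative gene Btg2 at 1.81 ± 0.59 and Aen at 1.09 ± 0.29. A median of 0.79 gave camera adjusted p = 4.18e-06, and 0.011 with an estimated correlation. Antioxidant genes rose too, Nqo1 by 2.06 ± 0.33, heme oxygenase Hmox1 by 1.54 ± 0.51 and Gstm3 by 2.12 ± 0.56, and 7 of 18 members rose (9 over the list alone). A median of 0.67 gave camera adjusted p = 1.49e-04, and 0.398 with an estimated correlation.

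Of the fatty acid synthesis genes at 48 h in young livers, 8 of 18 members fell (9 over the list alone), including Acss2 (-1.64 ± 0.57), Acacb (-1.22 ± 0.28) and the desaturase gene Scd1 (-1.17 ± 0.40). A median of -0.62 gave camera adjusted p = 5.26e-04, and 0.473 with an estimated correlation. Of the bile acid genes, 6 of 20 members fell (6 over the list alone), including Cyp8b1 (-2.89 ± 0.68), Slc27a5 (-1.15 ± 0.16) and Cyp27a1 (-1.08 ± 0.13). A median of -0.66 gave camera adjusted p = 0.00428, and 0.566 with an estimated correlation. The amino acid catabolism genes Hal (-1.45 ± 0.36) and Agxt (-1.03 ± 0.25) fell, and 1 of 21 members rose and 4 fell (1 and 5 over the list alone). A median of -0.33 gave camera adjusted p = 0.0304, and 0.707 with an estimated correlation. Cebpa (-1.31 ± 0.19), the clock output gene Dbp (-2.62 ± 0.78) and the uridine phosphorylase gene Upp2 (-3.97 ± 0.76) fell. Of the bile duct list Prom1 rose by 1.96 ± 0.47, Krt18 by 1.42 ± 0.31 and Krt8 by 1.35 ± 0.35, in cells not identified. A median of 0.19 gave camera adjusted p = 0.0221, and 0.566 with an estimated correlation. D17H6S56E-5 (5.10 ± 0.61) rose at 48 h in young livers. Arrdc3 (-3.04 ± 0.43), Mup10 (-2.97 ± 0.57) and Sult2a8 (-2.87 ± 0.89) fell. Mcm5 (3.61 ± 0.62), Mcm7 (2.30 ± 0.38), Trp53inp1 (1.31 ± 0.32), Gstm2 (1.42 ± 0.49) and Krt23 (0.73 ± 0.24) rose in these lists. Hsd3b7 (-0.98 ± 0.33), Aacs (-1.31 ± 0.44), Tdo2 (-0.93 ± 0.16) and Otc (-0.69 ± 0.19) fell in these lists. Ccnd1 (2.98 ± 0.54), Ccna2 (3.08 ± 0.40), Pcna (1.83 ± 0.26), Top2a (3.41 ± 0.57), Cebpb (0.60 ± 0.14) and Afp (1.01 ± 0.23) rose. Igfbp1 (2.66 ± 0.71) rose too. Ccne1 (0.48 ± 0.22), Foxm1 (0.35 ± 0.14), Smarca2 (-0.12 ± 0.40), Hnf4a (0.03 ± 0.09), Alb (-0.03 ± 0.05) and Cyp7a1 (-0.95 ± 0.72) did not pass. Saa2 (0.28 ± 0.57), Lcn2 (1.14 ± 0.51), Arntl (0.53 ± 0.40) and Igf1 (0.14 ± 0.08) did not pass. limma called 3340 genes (2012 higher and 1328 lower), against 1537 higher and 1794 lower with quantile normalization repeated. The count was 1297 without young sham 48 h replicate 1, 1819 without young sham 48 h replicate 2 and 1985 without young PH 48 h replicate 1. 20 of the 47 genes named as passing lost it with 1 array left out, most often without young sham 48 h replicate 1 (19). The amino acid list did not pass without young sham 48 h replicate 1 (median -0.31) or young PH 48 h replicate 1 (median -0.26), and the bile duct list without the latter (median 0.17, against 0.32 without replicate 2).

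In old livers at 24 h Rrm2 was at 1.81 ± 0.60, Mcm6 at 0.64 ± 0.58 and Ccnd1 at -0.08 ± 0.54, none past the threshold. In the S phase list 1 of 32 members fell (1 over the list alone), and the list did not pass (median 0.12, camera adjusted p = 0.489). Stress and early response genes rose, among them Ier3 (3.30 ± 0.97), Egr1 (2.95 ± 0.72), Fos (2.38 ± 0.56) and the phosphatase gene Dusp1 (2.13 ± 0.60), and 10 of 17 members rose (13 over the list alone). A median of 1.25 gave camera adjusted p = 8.94e-08, and 0.324 with an estimated correlation. Against 0 h its mean score was 0.70 after PH and -0.67 after sham. Igfbp1 rose by 4.76 ± 0.71, Cdkn1a by 3.40 ± 0.46, the chemokine genes Cxcl3 by 4.12 ± 0.89 and Cxcl2 by 3.75 ± 0.94, the lipid droplet gene Cidec by 4.27 ± 1.07 and the pyruvate dehydrogenase kinase gene Pdk4 by 3.91 ± 0.99. Ribosome biogenesis genes rose, Nhp2 by 1.27 ± 0.29, Nop58 by 1.13 ± 0.29 and Gar1 by 1.06 ± 0.25, and 11 of 24 members rose (18 over the list alone). A median of 0.61 gave camera adjusted p = 2.73e-10, and 0.324 with an estimated correlation, and the median was 0.35 without old PH 24 h replicate 1.

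Of the interferon list in old livers at 24 h, 14 of 27 members fell (19 over the list alone), including Ifit1 (-2.29 ± 0.48), Gbp3 (-2.00 ± 0.48) and Irf7 (-1.79 ± 0.38). A median of -0.98 gave camera adjusted p = 1.89e-10, and 0.324 with an estimated correlation. Against 0 h the mean score of this list was -0.60 after PH and 0.31 in the shams at 24 h, but -0.60 and -0.50 in the shams at 38 and 48 h. Of the cytochrome P450 and drug metabolism genes, 1 of 28 members rose and 11 fell (1 and 19 over the list alone), including Fmo1 (-2.16 ± 0.61), Cyp2c54 (-1.87 ± 0.49) and Cyp2f2 (-1.65 ± 0.35). A median of -0.82 gave camera adjusted p = 1.54e-06, and 0.324 with an estimated correlation, and the median was -0.54 without old sham 24 h replicate 1. Of the bile acid genes, 8 of 20 members fell (12 over the list alone), including Cyp8b1 (-3.08 ± 0.68), Akr1d1 (-2.26 ± 0.55) and the uptake transporter gene Slc10a1 (-1.69 ± 0.46). A median of -0.83 gave camera adjusted p = 7.95e-07, and 0.324 with an estimated correlation. Amino acid genes fell likewise, Prodh (-2.05 ± 0.50) and Hpd (-1.51 ± 0.41), and 8 of 21 members fell (11 over the list alone). A median of -0.71 gave camera adjusted p = 3.26e-07, and 0.324 with an estimated correlation. Pericentral genes were lower, Tbx3 (-2.31 ± 0.50) and Cyp1a2 (-1.39 ± 0.40), and 8 of 15 members fell (12 over the list alone). A median of -0.98 gave camera adjusted p = 1.53e-08, and 0.324 with an estimated correlation. Cebpa (-1.34 ± 0.19), Dbp (-2.94 ± 0.78) and Upp2 (-3.71 ± 0.76) fell. Median r with the group was 0.965, 0.98 and 0.971 for replicates 1 to 3 of old PH at 24 h. The median within groups was 0.993. Mup10 (-3.55 ± 0.57), Sult2a8 (-3.34 ± 0.89) and Serpina6 (-3.08 ± 0.60) fell at 24 h in old livers. Nolc1 (0.99 ± 0.18) rose in these lists. Mcm10 (-1.97 ± 0.49), Cyp2c37 (-1.54 ± 0.43), Hsd3b7 (-1.02 ± 0.33), Glul (-1.21 ± 0.33), Fah (-1.13 ± 0.29) and Ifit3 (-1.78 ± 0.24) fell in these lists. Slc1a2 (-1.43 ± 0.32) and Rhbg (-1.27 ± 0.20) fell too. Cebpb (0.70 ± 0.14) and Afp (0.99 ± 0.23) rose. Ccne1 (0.16 ± 0.22), Ccna2 (0.34 ± 0.40), Cdk1 (-0.10 ± 0.50), Mki67 (-0.30 ± 0.66), Foxm1 (-0.13 ± 0.14) and Pcna (0.56 ± 0.26) did not pass. Top2a (-0.52 ± 0.57), Smarca2 (-0.77 ± 0.40), Hnf4a (-0.23 ± 0.09), Alb (0.00 ± 0.05), Cyp7a1 (-1.94 ± 0.72) and Saa2 (-0.28 ± 0.57) did not pass. Lcn2 (0.23 ± 0.51), Arntl (0.65 ± 0.40) and Igf1 (-0.04 ± 0.08) did not pass. limma called 2058 genes (1367 higher and 691 lower), against 1003 higher and 841 lower with quantile normalization repeated. The count was 515 without old sham 24 h replicate 1, 564 without old sham 24 h replicate 2, 781 without old PH 24 h replicate 1, 1259 without old PH 24 h replicate 2 and 3859 without old PH 24 h replicate 3, and 1 in a fit on the 5 arrays compared, where young livers gave 897, so the order of the ages turns. With pooled shams it was 5234. 35 of the 43 genes named as passing lost it with 1 array left out, most often without old sham 24 h replicate 1 (31).

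At 38 h in old livers replication genes had risen. Rrm2 rose by 3.50 ± 0.60, Mcm6 by 2.57 ± 0.58, Mcm5 by 2.39 ± 0.62 and Mcm4 by 1.93 ± 0.37, and 19 of 32 members rose (25 over the list alone). A median of 1.00 gave camera adjusted p = 1.01e-15, and 0.186 with an estimated correlation. Mitotic genes past the threshold were Cdca8 (2.07 ± 0.47), Cdk1 (1.88 ± 0.50) and Nusap1 (1.73 ± 0.40) among others, and 5 of 34 members rose (23 over the list alone), with list median 1.07, camera adjusted p = 6.04e-12, and 0.36 with an estimated correlation, while Mki67 was at 2.03 ± 0.66 and Top2a at 1.83 ± 0.57. Without old PH 38 h replicate 1 the median was 0.45. Egr1 (3.26 ± 0.72), Cdkn1a (2.45 ± 0.46), the tubulin gene Tubb6 (2.80 ± 0.44), the lipid droplet gene Cidea (2.53 ± 0.56) and Lcn2 (1.90 ± 0.51) rose.

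Bile acid synthesis genes fell at 38 h in old livers, Cyp8b1 (-3.28 ± 0.68) and Cyp7a1 (-2.89 ± 0.72), the rate-limiting enzyme of the pathway, and 7 of 20 members fell (9 over the list alone). A median of -0.79 gave camera adjusted p = 9.24e-10, and 0.153 with an estimated correlation. Amino acid catabolism genes fell, Hal (-1.79 ± 0.36), Prodh (-1.76 ± 0.50) and Asl (-1.28 ± 0.31), and 6 of 21 members fell (15 over the list alone). A median of -0.68 gave camera adjusted p = 6.95e-12, and 0.184 with an estimated correlation. Periportal genes were lower, Etnppl (-2.14 ± 0.59) and Cyp2f2 (-1.52 ± 0.35), and 1 of 14 members rose and 4 fell (1 and 7 over the list alone). A median of -0.69 gave camera adjusted p = 3.08e-05, and 0.153 with an estimated correlation. Cebpa (-0.67 ± 0.19), Csad (-2.83 ± 0.48), the succinate receptor gene Sucnr1 (-2.84 ± 0.73) and Upp2 (-3.44 ± 0.76) fell. Replicate 3 of old PH at 38 h stood apart beside these groups, at a median r of 0.946 with its group, and without it the bile acid median was -0.47 and the amino acid median -0.33. Mad2l1 (1.44 ± 0.33) and Apoa4 (1.26 ± 0.22) rose in these lists at 38 h in old livers. Akr1d1 (-1.98 ± 0.55), Baat (-1.30 ± 0.14) and Otc (-1.21 ± 0.19) fell in these lists. Ccne1 (0.81 ± 0.22), Pcna (1.09 ± 0.26) and Cebpb (0.92 ± 0.14) rose. Ccnd1 (1.5 ± 0.54), Ccna2 (1.31 ± 0.40), Foxm1 (0.22 ± 0.14), Smarca2 (-1.03 ± 0.40), Hnf4a (0.00 ± 0.09) and Alb (-0.02 ± 0.05) did not pass. Afp (0.41 ± 0.23), Igfbp1 (1.57 ± 0.71), Saa2 (0.35 ± 0.57), Arntl (-1.28 ± 0.40), Dbp (2.39 ± 0.78) and Igf1 (0.03 ± 0.08) did not pass. limma called 871 genes (418 higher and 453 lower), against 297 higher and 615 lower with arrays centred on their medians. The count was 345 without old sham 38 h replicate 1, 96 without old sham 38 h replicate 2, 1670 without old PH 38 h replicate 2 and 549 without old PH 38 h replicate 3, and 0 in a fit on the 5 arrays compared, against 3865 genes at an unadjusted p under 0.05 in the fit of all arrays. 26 of the 31 genes named as passing lost it with 1 array left out, most often without old sham 38 h replicate 2 (25).

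By 48 h mitotic genes had risen in old livers. Birc5 rose by 5.49 ± 0.73, Ube2c by 4.96 ± 0.63, Ect2 by 4.87 ± 0.48, Mki67 by 4.82 ± 0.66 and Cdk1 by 4.18 ± 0.50, and 32 of 34 members rose (32 over the list alone). A median of 3.13 gave camera adjusted p = 1.32e-44, and 0.0402 with an estimated correlation. Rrm2 (4.02 ± 0.60), Mcm5 (3.62 ± 0.62) and Mcm6 (3.15 ± 0.58) rose, and 26 of 32 members rose and 1 fell (27 and 2 over the list alone). A median of 1.35 gave camera adjusted p = 3.62e-18, and 0.189 with an estimated correlation. Cyclin D1 rose by 2.52 ± 0.54 and Rbl1 by 2.98 ± 0.45, and 8 of 20 members rose (12 over the list alone). A median of 0.47 gave camera adjusted p = 1.08e-05, and 0.0181 with an estimated correlation. Cdkn1a (2.92 ± 0.46) and Eda2r (1.15 ± 0.19) rose among p53 targets, where 7 of 18 members rose (10 over the list alone). A median of 0.59 gave camera adjusted p = 2.44e-05, and 0.0181 with an estimated correlation.

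Collagen genes rose in old livers at 48 h, Col3a1 by 2.44 ± 0.69, Col1a1 by 2.23 ± 0.68 and Col4a1 by 1.60 ± 0.44, and 8 of 22 members rose and 1 fell (10 and 1 over the list alone). A median of 0.73 gave camera adjusted p = 3.59e-05, and 0.484 with an estimated correlation. Genes of antibody-producing cells fell, Iglv1 (-3.17 ± 0.73), Ighm (-2.25 ± 0.64) and Jchain (-2.09 ± 0.65), and 3 of 17 members fell (6 over the list alone). A median of -0.60 gave camera adjusted p = 0.00529, and 0.484 with an estimated correlation, and the median was -0.36 without old sham 48 h replicate 2. The lipogenic gene Thrsp (-2.98 ± 0.79), Scd1 (-1.41 ± 0.40) and Srebf1 (-1.28 ± 0.37) fell, and 7 of 18 members fell (8 over the list alone). A median of -0.57 gave camera adjusted p = 0.00422, and 0.496 with an estimated correlation. Dbp (-3.07 ± 0.78), Cebpa (-1.33 ± 0.19) and Upp2 (-3.47 ± 0.76) fell as well, and Igfbp1 (3.90 ± 0.71) rose. D17H6S56E-5 (5.02 ± 0.61) rose at 48 h in old livers. Mup10 (-3.27 ± 0.57) fell. Rfc4 (2.29 ± 0.30), Cdkn2c (2.88 ± 0.42), Trp53inp1 (1.04 ± 0.32), Phlda3 (0.96 ± 0.19) and Lum (1.59 ± 0.36) rose in these lists. Acacb (-1.21 ± 0.28) fell in these lists. Ccna2 (2.68 ± 0.40), Pcna (1.58 ± 0.26), Top2a (3.68 ± 0.57) and Cebpb (0.63 ± 0.14) rose. Ccne1 (0.35 ± 0.22), Foxm1 (0.25 ± 0.14), Smarca2 (-0.10 ± 0.40), Hnf4a (-0.14 ± 0.09), Alb (0.01 ± 0.05) and Afp (0.39 ± 0.23) did not pass. Cyp7a1 (-0.85 ± 0.72), Saa2 (-0.11 ± 0.57), Lcn2 (0.81 ± 0.51), Arntl (1.13 ± 0.40) and Igf1 (0.20 ± 0.08) did not pass. limma called 2733 genes (1539 higher and 1194 lower), against 1198 higher and 1438 lower with quantile normalization repeated. The count was 1155 without old sham 48 h replicate 1, 908 without old sham 48 h replicate 2, 1726 without old PH 48 h replicate 1 and 1764 without old PH 48 h replicate 2. 15 of the 37 genes named as passing lost it with 1 array left out, most often without old sham 48 h replicate 2 (12).

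The ages were then compared directly after PH. At 24 h old livers had less replication transcript, with Mcm6 (-2.14 ± 0.52), Mcm10 (-2.07 ± 0.44), Mcm5 (-1.83 ± 0.55), Ccne2 (-1.79 ± 0.35) and Cdk1 (-1.47 ± 0.45) lower than in young livers, and 14 of 32 members were lower (26 over the list alone). A median of -0.73 gave camera adjusted p = 3.95e-12, and 0.378 with an estimated correlation. The phospholyase gene Etnppl was lower (-3.75 ± 0.53), and amino acid genes such as Cth (-2.03 ± 0.52) and Oat (-1.64 ± 0.46) were lower, where 15 of 21 members were lower (17 over the list alone). A median of -0.88 gave camera adjusted p = 7.63e-12, and 0.378 with an estimated correlation. Cxcl3 (3.80 ± 0.80), Cxcl2 (3.46 ± 0.84), the endotoxin co-receptor gene Cd14 (3.24 ± 0.92), Cidec (3.47 ± 0.95) and Cdkn1a (2.05 ± 0.41) were higher in old livers. Pdk4 (3.26) was higher in old livers at 24 h after PH. Hectd2os (-3.12), Cyp4a14 (-2.95), Keg1 (-2.80) and Ddc (-2.68) were lower. Prodh (-1.76) and Hpd (-1.56) were lower in these lists. Foxm1 (-0.43), Cebpa (-0.76) and Igf1 (-0.28) were lower. Between the ages at 24 h after PH, panel genes not passing ran from Top2a (-1.59) to Igfbp1 (1.42), with standard errors of lone values up to 0.89. limma called 1345 genes (822 higher and 523 lower), against 622 higher and 624 lower with quantile normalization repeated. The count was 670 without young PH 24 h replicate 1, 169 without young PH 24 h replicate 2, 332 without young PH 24 h replicate 3, 218 without old PH 24 h replicate 1, 256 without old PH 24 h replicate 2 and 3786 without old PH 24 h replicate 3, 0 in a fit on the 6 arrays compared against 4913 genes at an unadjusted p under 0.05 in the fit of all arrays. 22 of the 23 genes named as passing lost it with 1 array left out, most often without old PH 24 h replicate 1 (21).

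At 38 h cell cycle genes were lower in old livers. The kinetochore gene Nuf2 (-2.82 ± 0.39), Esco2 (-2.65 ± 0.53), Ccne2 (-2.44 ± 0.35), Birc5 (-2.60 ± 0.65), Mki67 (-2.26 ± 0.59) and Top2a (-2.19 ± 0.51) were lower in old livers, while Cidea (2.51 ± 0.50), the clock gene Nr1d1 (1.40 ± 0.27) and the plasma glutathione peroxidase gene Gpx3 (1.29 ± 0.31) were higher. In the S phase list 19 of 32 members were lower (28 over the list alone), with list median -1.12, camera adjusted p = 7.49e-33, and 0.0677 with an estimated correlation, and in the mitosis list 18 of 34 members were lower (30 over the list alone). A median of -1.29 gave camera adjusted p = 4.74e-30, and 0.101 with an estimated correlation, and the median was -0.80 without old PH 38 h replicate 3. Among G1 regulators 5 of 20 members were lower (10 over the list alone). A median of -0.33 gave camera adjusted p = 5.75e-07, and 0.0142 with an estimated correlation. Wfdc2 (1.11) and Tns2 (0.95) were higher in old livers at 38 h after PH. D17H6S56E-5 (-2.56) and 4930579G24Rik (-2.23) were lower. Prim1 (-1.88), Cdc6 (-1.85), Rfc4 (-1.59), Ect2 (-2.15), Rbl1 (-1.63) and Cdkn2c (-1.62) were lower in these lists. E2f1 (-1.01) and Cdk2 (-0.55) were lower too. Cdk1 (-2.02) and Pcna (-1.07) were lower. Between the ages at 38 h after PH, panel genes not passing ran from Mcm6 (-1.90) to Dbp (1.38), with standard errors of lone values up to 0.70. limma called 366 genes (92 higher and 274 lower), and the count was 222 without young PH 38 h replicate 2, 88 without young PH 38 h replicate 3, 678 without old PH 38 h replicate 1, 565 without old PH 38 h replicate 2 and 49 without old PH 38 h replicate 3, and 0 in a fit on the 6 arrays compared against 3135 genes at an unadjusted p under 0.05 in the fit of all arrays. 17 of the 23 genes named as passing lost it with 1 array left out, most often without old PH 38 h replicate 3 (17).

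At 48 h few genes differed by age after PH. Nebl (1.21 ± 0.22), Gm7969 (1.10 ± 0.17) and Zfp991 (1.03 ± 0.19) were higher in old livers, and the macrophage scavenger receptor gene Cd163 (-1.38 ± 0.24), Amn (-0.93 ± 0.13) and Wdfy1 (-0.87 ± 0.13) were lower. In the S phase list 0 of 32 members passed in limma (0 over the list alone, 3 at an unadjusted p under 0.05). A median of -0.28 gave camera adjusted p = 9.73e-05, and 0.679 with an estimated correlation, and the median was -0.15 without old PH 48 h replicate 1. Crygn (0.83) and Wfdc15b (0.74) were higher in old livers at 48 h after PH. Lysmd2 (-0.81) and Mrps6 (-0.59) were lower. Between the ages at 48 h after PH, panel genes not passing ran from Rrm2 (-0.63) to Lcn2 (0.35), with standard errors of lone values up to 0.53. Fen1 (-0.09) did not pass. limma called 15 genes (10 higher and 5 lower), and the count was 5 without young PH 48 h replicate 1, 3 without young PH 48 h replicate 3, 5 without old PH 48 h replicate 1, 0 without old PH 48 h replicate 2 and 3 without old PH 48 h replicate 3. For the count of 0 without old PH 48 h replicate 2, 1293 genes had an unadjusted p under 0.05 in the fit of all arrays. 10 of the 10 genes named as passing lost it with 1 array left out, most often without old PH 48 h replicate 2 (10).

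Whether the response to PH itself differed by age was tested as the difference between old and young of PH minus sham. At 24 h limma called 0 genes (1677 at an unadjusted p under 0.05) and at 48 h 0 genes (378 unadjusted), and over the mean of the times 0 genes (1871 unadjusted). At 38 h, where the young response rests on a single sham array, it called 16 genes (9 higher and 7 lower). Car9, a carbonic anhydrase, was higher by 1.08 ± 0.14 in the old response (-0.05 with 0 h livers as control) and Muc3 by 0.95 ± 0.17, and the purine synthesis gene Pfas (-1.30 ± 0.24), Rpl22l1 (-1.27 ± 0.24), the splicing regulator Mbnl2 (-1.26 ± 0.25) and Cnot7 (-1.10 ± 0.22) were lower. Other genes of the count were Zfp536 (0.94 ± 0.18), Fads2b (0.86 ± 0.16) and Pcbp4 (-0.97 ± 0.19). 1700018A04Rik (0.94) was higher in the age difference of the response at 38 h. In the age difference of the response at 38 h, panel genes not passing ran from Igfbp1 (-2.71) to Dbp (1.43), with standard errors of lone values up to 1.26. Fen1 (0.03) did not pass. With arrays centred on their medians the split at 38 h was 8 higher and 3 lower, and with quantile normalization repeated 23 higher and 5 lower. It was 0 without the dimmest 40% of genes (2646 genes at an unadjusted p under 0.05 in the fit of all) and 1 in a fit on the arrays compared. The 24 h count was 13 without old sham 24 h replicate 1, 2 without old sham 24 h replicate 2 and 3 without young PH 24 h replicate 3, the 38 h count 6 without old sham 38 h replicate 1, 1 without young PH 38 h replicate 3, 97 without old PH 38 h replicate 1, 93 without old PH 38 h replicate 2 and 4 without old PH 38 h replicate 3, the 48 h count 1 without old sham 48 h replicate 1 and the count over the mean of the times 7 without old sham 38 h replicate 2, 1 without old sham 48 h replicate 1, 2 without young PH 24 h replicate 3 and 1 without old PH 38 h replicate 1. 9 of the 10 genes named as passing lost it with 1 array left out, most often without young PH 38 h replicate 3 (9).

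In the age difference of the response at 24 h, panel genes not passing ran from Cyp7a1 (-2.43) to Igfbp1 (2.72), with standard errors of lone values up to 1.02. Fen1 (-0.06) did not pass. At 48 h panel genes ran from Afp (-0.62) to Igfbp1 (1.25), with standard errors of lone values up to 1.01. Over all times they ran from Rrm2 (-1.22) to Igfbp1 (0.42), with standard errors of lone values up to 0.61. As lists, S phase genes responded less in old than in young livers at 24 h, with list median -0.79, camera adjusted p = 6.02e-12, and 0.35 with an estimated correlation, and at 38 h, with list median -1.16, camera adjusted p = 1.63e-12, and 0.323 with an estimated correlation (median -0.70 without old PH 38 h replicate 3). At 24 h 0 of 32 members passed in limma (0 over the list alone, 12 at an unadjusted p under 0.05), and at 38 h 0 of 32 members passed in limma (12 over the list alone, 21 at an unadjusted p under 0.05). Over all 18193 genes the slope of the old on the young log2 change was 0.79 at 24 h (Pearson r 0.47), 0.44 at 38 h (r 0.53) and 0.85 at 48 h (r 0.91). Across the genes past the threshold in either age, at 24 h 2058 called in old and 129 in young livers, the slope was 1.45 at 24 h (2122 genes, Pearson r 0.69), 0.57 at 38 h (1726 genes, r 0.76) and 0.89 at 48 h (4216 genes, r 0.95). These are relations across genes, which are not independent replicates. Leaving out 1 array gave slopes over these genes of 1.01 to 1.71, 0.49 to 0.67 and 0.83 to 0.96. The young sham array at 38 h was never left out, and over genes called against 0 h that slope was 0.72.

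Sham surgery was compared with untreated livers as the mean of the 3 sham times. In young livers the acute phase genes rose, serum amyloid A2 (Saa2) by 4.20 ± 0.46, lipocalin 2 (Lcn2) by 4.10 ± 0.42, orosomucoid 2 (Orm2) by 3.63 ± 0.60 and Saa1 by 2.64 ± 0.33, and 12 of 26 members rose and 1 fell (13 and 1 over the list alone). A median of 0.36 gave camera adjusted p = 8.01e-05, and 0.664 with an estimated correlation. Of 15 neutrophil markers 4 rose (4 over the list alone), Lcn2 again among them. A median of 0.32 gave camera adjusted p = 0.0179, and 0.742 with an estimated correlation, and the mean score was 0.76, 0.58 and 0.53 in shams at 24, 38 and 48 h against 0 h. The list did not pass without young 0 h replicate 1 (median 0.28). The phosphatidate phosphatase gene Lpin1 (-3.92 ± 0.29), Gadd45g (-2.70 ± 0.39), Dusp1 (-2.71 ± 0.49), Igfbp1 (-2.93 ± 0.58) and Dbp (-1.98 ± 0.64) fell. Heat shock genes fell, Hspa1b (-2.53 ± 0.68) and Hsph1 (-1.37 ± 0.37), and 8 of 14 members fell (11 over the list alone). A median of -0.61 gave camera adjusted p = 0.00437, and 0.664 with an estimated correlation. Of the list of C/EBP proteins and chromatin repressors, 9 of 14 members fell (10 over the list alone), including Sirt1 (-1.18 ± 0.17) and Smarca2 (-1.08 ± 0.33). A median of -0.44 gave camera adjusted p = 7.34e-04, and 0.0462 with an estimated correlation. Clock genes fell, Nr1d2 (-1.52 ± 0.29) and Clock (-1.10 ± 0.18), and 9 of 19 members fell (10 over the list alone). A median of -0.57 gave camera adjusted p = 0.00661, and 0.468 with an estimated correlation. The beta-actin 3' minus 5' difference was 0.80 ± 0.08 (SD, n = 3) in young 0 h arrays and 0.49, 0.80 and 0.54 in young shams at 24, 38 and 48 h. The BioB spike-in level was 8.66 ± 0.05 (SD) at 0 h and 9.20, 8.04 and 9.16 in these shams. Malat1 (1.87) rose after sham surgery in young livers. Upp2 (-2.63) fell. Cxcr2 (0.43), Elane (0.38) and Csf3r (0.32) rose in these lists. Cebpd (-1.46), Rbl2 (-1.04), Noct (-1.13), Hsp90aa1 (-0.66) and Dnajb1 (-0.66) fell in these lists. Ccne1 (0.98) rose. Cdkn1a (-1.24), Cebpb (-0.74) and Hnf4a (-0.39) fell. After sham surgery in young livers, panel genes not passing ran from Rrm2 (-1.21) to Cdk1 (0.17), with standard errors of lone values up to 0.62. limma called 6121 genes (3007 higher and 3114 lower). 7 of the 29 genes named as passing lost it with 1 array left out, most often without young control 0 h replicate 1 (6).

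In old livers the same surgery gave Bmf, a pro-apoptotic gene, a rise of 1.94 ± 0.19, with Malat1 at 1.66 ± 0.35 and Saa2 at 1.57 ± 0.44, while Lcn2 (0.91 ± 0.40) did not pass. Early response and heat shock genes fell, Fos (-2.34 ± 0.43), Egr1 (-2.63 ± 0.56), Klf10 (-2.55 ± 0.39), Hspa1b (-2.65 ± 0.65) and Hspa1a (-2.27 ± 0.64). In the heat shock list 8 of 14 members fell (8 over the list alone), with list median -0.55, camera adjusted p = 7.24e-04, and 0.671 with an estimated correlation, and in the early response list 7 of 17 members fell (7 over the list alone). A median of -0.36 gave camera adjusted p = 0.00564, and 0.785 with an estimated correlation, and the median was -0.22 without old 0 h replicate 2. The beta-actin 3' minus 5' difference was 0.89 ± 0.16 (SD, n = 3) in old 0 h arrays and 0.72, 0.74 and 0.56 in old shams at 24, 38 and 48 h. Zfp3 (1.65), Zfy2 (1.34) and Bpifb1 (1.33) rose after sham surgery in old livers. Dusp1 (-2.47) fell. Jun (-2.10), Hsph1 (-1.24) and Hspa4l (-0.82) fell in these lists. Ccne1 (0.73) rose. Cebpb (-0.55) and Igfbp1 (-2.13) fell. After sham surgery in old livers, panel genes not passing ran from Rrm2 (-0.91) to Lcn2 (0.91), with standard errors of lone values up to 0.55. limma called 5161 genes (2862 higher and 2299 lower), and the count was 2928 without old control 0 h replicate 1 and 3196 without old control 0 h replicate 2. 4 of the 18 genes named as passing lost it with 1 array left out, most often without old control 0 h replicate 1 (2).

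PH livers were also compared with 0 h livers of the same age, a comparison that includes the operation. In young livers Lcn2 rose by 5.07 ± 0.46 and Saa2 by 4.50 ± 0.51 at 24 h, and Lcn2 by 5.01 ± 0.46 at 38 h and 4.56 ± 0.46 at 48 h, while Upp2 fell, with changes of -3.54 ± 0.68, -4.98 ± 0.68 and -5.0 ± 0.68. In old livers Lcn2 rose by 2.08 ± 0.46, 1.83 ± 0.46 and 1.76 ± 0.46, and Upp2 fell, with changes of -5.96 ± 0.68, -5.17 ± 0.68 and -5.05 ± 0.68. Smarca2, a chromatin remodelling ATPase, was at -0.70 ± 0.36, -1.06 ± 0.36 and -1.13 ± 0.36 in young and -1.42 ± 0.36, -1.83 ± 0.36 and -1.02 ± 0.36 in old livers, each a fall except the young value at 24 h. Cebpb ran from -0.13 to 0.26 over both ages and did not pass, and Igfbp1 passed in old livers at 24 h alone (2.11). Orm2 (3.84), Cyp4a14 (3.66) and Ly6d (3.10) rose at 24 h against 0 h in young livers. Mme (-3.34), Inmt (-3.15), Thrsp (-2.71) and Lpin1 (-2.52) fell. Ccnd1 (1.57), Ccne1 (1.11), Cdk1 (1.37), Pcna (1.15), Mcm6 (2.65) and Rrm2 (1.76) rose. Igf1 (0.22) rose too. Cebpa (-0.57), Hnf4a (-0.33) and Dbp (-2.09) fell. Panel genes not passing ran from Cyp7a1 (-0.89) to Top2a (1.09), with standard errors of lone values up to 0.87. D17H6S56E-5 (4.87), Birc5 (4.68), Saa2 (4.34) and Esco2 (4.19) rose at 38 h against 0 h in young livers. Inmt (-3.51), Mup10 (-3.50), Cyp8b1 (-3.43) and Hsd3b5 (-3.21) fell. Ccnd1 (2.51), Ccne1 (2.25), Ccna2 (2.26), Cdk1 (3.77), Mki67 (3.89), Pcna (2.35), Mcm6 (3.97), Rrm2 (4.11), Top2a (3.55), Cdkn1a (1.75) and Afp (0.77) rose. Cebpa (-1.25), Hnf4a (-0.48) and Dbp (-2.83) fell. Panel genes not passing ran from Cyp7a1 (-1.33) to Igfbp1 (0.46), with standard errors of lone values up to 1.22. Birc5 (5.90), D17H6S56E-5 (5.50), Ube2c (5.15) and Mki67 (4.97) rose at 48 h against 0 h in young livers. Hsd3b5 (-3.83), Serpina4-ps1 (-3.71), Dbp (-3.60) and Lpin1 (-3.55) fell. Ccnd1 (2.63), Ccne1 (1.32), Ccna2 (3.20), Cdk1 (4.37), Pcna (1.66), Mcm6 (2.90), Rrm2 (3.47), Top2a (3.58), Cdkn1a (1.95), Afp (0.73) and Saa2 (4.03) rose. Cebpa (-1.29) and Hnf4a (-0.37) fell. Panel genes not passing ran from Cyp7a1 (-0.96) to Foxm1 (0.28), with standard errors of lone values up to 1.22. Cidec (4.37), Cxcl3 (4.22), Ly6d (3.74), Tnfrsf12a (3.39) and Ier3 (3.39) rose at 24 h against 0 h in old livers. Inmt (-4.22), Hsd3b5 (-3.99), Mup10 (-3.72) and Akr1c14 (-3.71) fell. Outlying replicate 1 had log2 levels of 5.78 for Akr1c14 and 12.45 for Cidec (mean of others 10.8 and 9.63). Ccne1 (0.99), Cdkn1a (3.07), Afp (0.92), Igfbp1 (2.11) and Saa2 (1.85) rose. Cebpa (-1.25), Hnf4a (-0.22), Cyp7a1 (-2.74) and Dbp (-1.94) fell. Panel genes not passing ran from Mki67 (-0.77) to Rrm2 (1.01), with standard errors of lone values up to 1.22. Cidec (2.89), Rrm2 (2.76), Ly6d (2.74), Tubb6 (2.72) and Fabp4 (2.28) rose at 38 h against 0 h in old livers. 9130409I23Rik (-3.43), Sucnr1 (-3.34), Akr1c14 (-3.32) and Cyp8b1 (-3.27) fell. Outlying replicate 3 had levels of 5.42 for Akr1c14 and 12.25 for Cidec (mean of others 11.57 and 7.5). Ccnd1 (1.24), Ccne1 (1.63), Ccna2 (0.95), Cdk1 (1.62), Pcna (1.01), Mcm6 (2.22), Cdkn1a (2.23) and Saa2 (1.61) rose. Cebpa (-0.74), Cyp7a1 (-2.36) and Arntl (-1.14) fell. Panel genes not passing ran from Dbp (-0.38) to Top2a (1.23), with standard errors of lone values up to 1.12. Birc5 (5.25), D17H6S56E-5 (5.00), Ube2c (4.88), Nuf2 (4.36) and Cdk1 (4.17) rose at 48 h against 0 h in old livers. Thrsp (-4.62), Arrdc3 (-3.36), Inmt (-3.18) and Cyp8b1 (-3.13) fell. Ccnd1 (2.52), Ccne1 (0.88), Ccna2 (2.63), Mki67 (4.14), Foxm1 (0.51), Pcna (1.14), Mcm6 (2.70), Rrm2 (2.81), Top2a (3.56) and Cdkn1a (2.52) rose. Cebpa (-1.09) and Dbp (-2.43) fell. Panel genes not passing ran from Cyp7a1 (-1.61) to Saa2 (1.19), with standard errors of lone values up to 0.76. In young livers limma called 3163 (1423 higher, 1740 lower), 5765 (2766, 2999) and 5073 (2441, 2632) genes at 24, 38 and 48 h. In old livers it called 4413 (2122, 2291), 6987 (3976, 3011) and 3075 (1507, 1568). With 1 array left out, 8 of 20, 2 of 25 and 3 of 25 named genes lost the threshold in young livers. In old livers 8 of 21, 8 of 23 and 3 of 24 did. The young 24 h count was 1748 without young control 0 h replicate 1, 1895 without young control 0 h replicate 3 and 2103 without young PH 24 h replicate 2, the old 24 h count 2811 without old control 0 h replicate 1 and 2747 without old PH 24 h replicate 1 and the old 48 h count 1956 without old control 0 h replicate 1 and 2040 without old PH 48 h replicate 2. The old counts at 24 and 38 h were 874 and 1010 in fits on the 6 arrays compared.

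**Figure D2:**
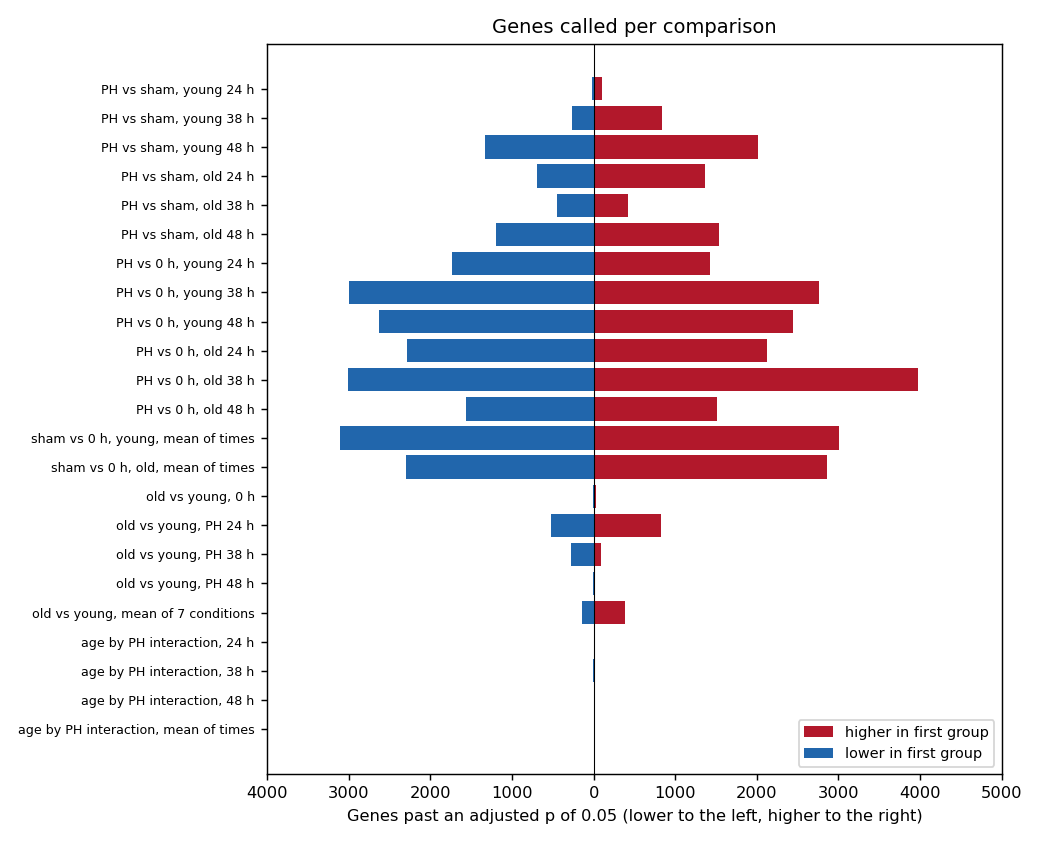
Number of genes past an adjusted p of 0.05 in each comparison, with genes higher in the first-named group to the right and lower to the left. The PH against sham counts are 129, 1103 and 3340 in young and 2058, 871 and 2733 in old livers at 24, 38 and 48 h.

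Untreated old and young livers differed in few genes. Lcn2 (3.14 ± 0.46) and Saa2 (2.39 ± 0.51), both acute phase genes, Zfp979 (2.00 ± 0.28), Dmrta1 (1.85 ± 0.22) and Cdh19 (1.64 ± 0.16) were higher in old livers, and Cd163 (-1.62 ± 0.24), Lpin1 (-1.59 ± 0.32), Ces2b (-0.90 ± 0.17), Wdfy1 (-0.89 ± 0.13) and Map3k5 (-0.74 ± 0.11) were lower. In the acute phase list 3 of 26 members were higher (10 over the list alone). A median of 0.17 gave camera adjusted p = 3.12e-09, and 0.818 with an estimated correlation, and the median was 0.30 without old 0 h replicate 1. Macrophage markers moved with age in this comparison, where 1 of 21 members were lower (9 higher and 1 lower over the list alone). A median of 0.87 gave camera adjusted p = 3.12e-09, and 0.869 with an estimated correlation. Lrtm1 (1.62) was higher in untreated old livers. Orm1 (0.46) was higher in these lists. Between untreated livers of the ages, panel genes not passing ran from Dbp (-1.07) to Mki67 (0.56), with standard errors of lone values up to 0.70. limma called 43 genes (32 higher and 11 lower), and the count was 25 without young control 0 h replicate 3, 81 without old control 0 h replicate 1 and 22 without old control 0 h replicate 2. 4 of the 12 genes named as passing lost it with 1 array left out, most often without young control 0 h replicate 3 (4). The macrophage list did not pass without old control 0 h replicate 2 (median 0.22). Between sham livers of the ages Lcn2 differed by -0.04, Saa2 by -0.25, Lpin1 by 0.26 and Map3k5 by 0.15, each with the sign turned.

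Averaged over the 7 conditions, old livers had more antibody transcript: Ighm was higher by 2.11 ± 0.25, Igkv8-30 by 1.99 ± 0.21 and Jchain, the joining chain, by 1.75 ± 0.25, and 6 of 17 members were higher (7 over the list alone). A median of 0.14 gave camera adjusted p = 7.24e-07, and 0.219 with an estimated correlation, and the median was 0.07 without old sham 24 h replicate 2. Bzw2 (1.13 ± 0.11), Gpx3 (1.03 ± 0.13) and Dmrta1 (1.01 ± 0.09) were higher. Etnppl (-1.43 ± 0.23), Cd163 (-1.03 ± 0.10), Acot1 (-1.03 ± 0.15), Slc39a4 (-0.88 ± 0.14) and Tceal8 (-0.80 ± 0.11) were lower. Heat shock genes were lower, Hsph1 (-0.77 ± 0.18), and 5 of 14 members were lower (10 over the list alone). A median of -0.34 gave camera adjusted p = 3.34e-09, and 0.219 with an estimated correlation. H2-Aa (0.99) and Cd74 (0.83) were higher in these lists in old livers over all conditions. Hspa4l (-0.38), Hsp90aa1 (-0.35) and Hspe1 (-0.26) were lower in these lists. Between the ages over all conditions, panel genes not passing ran from Mcm6 (-0.77) to Lcn2 (0.50), with standard errors of lone values up to 0.22. limma called 524 genes (386 higher and 138 lower), against 321 higher and 217 lower with quantile normalization repeated. The count was 329 without young sham 24 h replicate 2, 335 without young sham 48 h replicate 2, 338 without old sham 38 h replicate 2, 980 without old PH 24 h replicate 3 and 865 without old PH 38 h replicate 1. 17 of 17 genes named as past the threshold held without any 1 array.

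**Figure D3:**
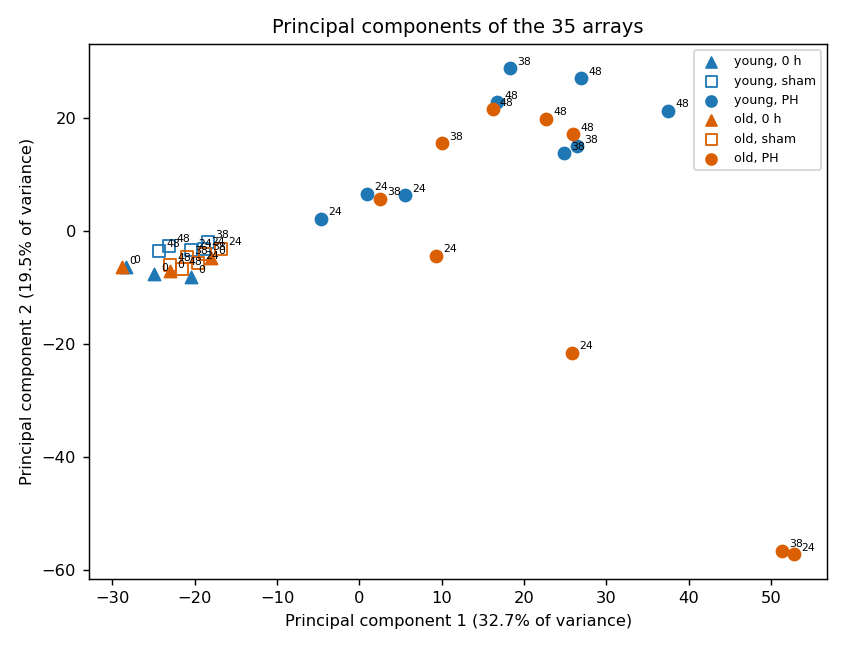
First and second principal component of the 35 arrays over 18193 genes, with age by colour, treatment by symbol and the time after surgery in hours beside each point. Replicates 1 and 2 of old PH at 24 h lie at -57.3 and -21.5 on the second component. Replicate 3 of old PH at 38 h lies at -56.7.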

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

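The tests of degradation, other cells, labels, 3' bias, spike-in controls, outlying arrays alone and the 0 h baseline were chosen after the results were seen, and so was leaving out 2 arrays. The counts over other splits of the arrays were planned.

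Replicate 1 of old PH at 24 h and replicate 3 of old PH at 38 h stood apart from their groups alike. Their deviations from the group means had r = 0.82 (at most 0.67 for other pairs). Chosen after their values were seen, Rab30 was higher by 4.83 and 5.14 and Sult1e1 by 4.17 and 5.94 than in the other arrays of the group, and Slco1b2 (-5.33 and -6.08) and Akr1c14 (-5.01 and -6.15) were lower. RNA of another cell type or tissue is argued against by the 10 marker lists, of which none rose by a median over 0.08 in both arrays, neutrophil being highest. A label of another group is argued against for the 24 h array, which correlated with no other group's mean above 0.17, where the other arrays had at least 0.37 with their own. For the 38 h array it stays open (0.53 with old PH at 24 h, above that 0.37). The array had 0.13 with its own group and 0.92 with the 24 h array. RNA degradation stays open because the beta-actin 3' minus 5' differences of 0.62 and 0.67 lie above the median of 0.59 of the other 7 old PH arrays. Of these 3 exceed both (highest 1.04, a looser bound tried and set aside as it rests on 1 array). No biological explanation was tested.

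Sham and 0 h livers differed in 6121 genes in young and 5161 genes in old mice. On an index set at 0 for the 0 h arrays and 1 for the other shams of an age, 3 old shams with a BioB level below that at 0 h and 3 above it were all at 0.90 or higher, which argues against hybridisation differences in old mice. In young mice (lowest index 0.85) a difference that runs with BioB stays open because 1 sham lies below, and 3' bias of the RNA stays open in both ages because 1 of 11 shams (index 1.34) has a beta-actin difference in the 0 h range of its age. The response to surgery and anaesthesia, named by the design, stays open too, as does any handling that all 0 h livers shared. Chance can be excluded in both ages, with 1 of 56 splits of the young and 1 of 84 of the old arrays giving as many genes, though the highest other splits gave 2983 and 1513 genes, which points to further structure among the arrays.

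S phase genes were lower in old than in young livers 24 and 38 h after PH by camera with a preset correlation, but not with an estimated one (adjusted p = 0.378 and 0.0677), nor by the score (exact p = 0.1 at both times, adjusted 0.285). Without both outlying arrays the mean score was still lower in old livers, by 0.99 at 24 h and 0.79 at 38 h (0.96 and 1.20 with them, pooled SD 0.34 and 0.28 without), so these arrays alone are argued against. Levels after PH not set against 0 h differed by medians of -0.73 or lower, which argues against the 0 h baseline. Age stays open as the biological difference named by the design, together with the supplier, from which it cannot be told apart.

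By camera with a preset correlation the response to PH differed between ages in these lists. With an estimated one it differed in 0 (lowest adjusted p 0.272, 0.166 and 0.63 at 24, 38 and 48 h). Values are list medians of old minus young log2 change. S phase (-0.79), mitosis (-0.40), cytochrome P450 (-0.59), bile acid (-0.75), gluconeogenesis (-0.39) and amino acid catabolism (-0.80) were lower in the old response at 24 h. So were male-biased genes (-0.70), interferon response (-0.65), heat shock (-0.33), pericentral hepatocyte (-1.14), macrophage and Kupffer cell (-0.70), B and plasma cell (-0.37) and adipose tissue (-0.42). Immediate early and priming (0.67) was higher. Old 24 h shams scored -0.3 and 0.84 (B cell), 0.14 and 0.87 (adipose). Outlying old PH replicate 1 was off by -0.78 (bile acid), -0.72 (male-biased), -0.67 (pericentral) and -0.6 (interferon), others by less. S phase (-1.16), mitosis (-1.13), G1 regulators (-0.36), C/EBP and chromatin repressors (-0.28), P450 (-0.54) and bile acid (-0.51) were lower in the old response at 38 h (1 young sham array). So were fatty acid synthesis (-0.38), amino acid catabolism (-0.70), NRF2 antioxidant (-0.55), pericentral (-0.68) and periportal hepatocyte (-0.81), stellate cell and matrix (-0.29) and sinusoidal endothelium (-0.38). Endoplasmic reticulum stress (0.37) and T and NK cell (0.24) were higher. Outlying old PH replicate 3 was off its group by -0.84 (P450), -1.38 (bile acid), -1.37 (mitosis), -1.23 (amino acid, pericentral) and -1.11 (S phase), others by less. B and plasma cell (-0.19) was lower at 48 h. Cholesterol synthesis (0.61), fatty acid oxidation and PPAR alpha (0.17), gluconeogenesis and glucose metabolism (0.27), plasma proteins and hepatocyte transcription factors (0.04), interferon response (0.25) and stellate cell and matrix (0.33) were higher in the old response at 48 h. At 38 h 16 genes passed.

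BioB, a spike-in control outside the comparisons, stood above the 0 h arrays in young sham livers at 24 h (9.20) and 48 h (9.16) and in old sham livers at 48 h (9.04).

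For groups of 3 against 3 arrays the 10 splits are too few for a share under 0.05. Against 0 h, PH gave 3163, 5765 and 5073 genes in young livers at 24, 38 and 48 h, with 0, 4 and 1 in the highest other split. In old livers it gave 4413, 6987 and 3075, with 4, 15 and 0. Old against young gave 43 genes at 0 h, where another split gave 105 and 2 of the 10 splits gave as many, and 1345, 366 and 15 after PH, with 3, 159 and 1 in the highest other split. Averaged over 7 conditions, chance can be excluded, with 524 genes against at most 7 in 100 splits.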

How the results depend on the processing

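Leaving out 2 outlying arrays was chosen after the results were seen, and the other alternatives were planned. Values are numbers of genes past the threshold, given where they differ over 1.5 times from those in the report and as ranges for leaving out 1 array, and the cause was not tested except where fewer or more genes or arrays enter a fit. Testing every probe set gave 266 (young 24 h), 1856 (young 38 h), 6549 (young 48 h), 3222 (old 24 h) and 5352 (old 48 h) for PH against sham. It gave 6840 (young 24 h), 13718 (young 38 h), 11567 (young 48 h), 9152 (old 24 h), 16703 (old 38 h) and 6372 (old 48 h) for PH against 0 h. It gave 14524 (young, mean) and 12785 (old, mean) for sham against 0 h. It gave 75 (0 h), 2034 (PH 24 h), 584 (PH 38 h), 32 (PH 48 h) and 870 (mean of 7 conditions) for old against young. It gave 41 (38 h) and 1 (mean) for the age difference of the response. Array weights gave 1712 (young 24 h), 3366 (young 38 h), 5998 (young 48 h), 6222 (old 24 h) and 6525 (old 48 h) for PH against sham. It gave 5994 (young 24 h), 8787 (young 38 h), 7647 (old 24 h) and 4685 (old 48 h) for PH against 0 h. It gave 143 (0 h), 8583 (PH 24 h), 165 (PH 48 h) and 2180 (mean of 7 conditions) for old against young. It gave 1987 (24 h), 209 (38 h), 3 (48 h) and 129 (mean) for the age difference of the response. Fitting the arrays compared alone gave 897 (young 24 h), 426 (young 38 h), 1 (old 24 h), 0 (old 38 h) and 4503 (old 48 h) for PH against sham. It gave 874 (old 24 h) and 1010 (old 38 h) for PH against 0 h. It gave 0 (PH 24 h) and 0 (PH 38 h) for old against young. It gave 1 (38 h) and 1 (48 h) for the age difference of the response. Pooling the shams of an age gave 1121 (young 24 h), 3224 (young 38 h), 5351 (young 48 h), 5234 (old 24 h) and 2436 (old 38 h) for PH against sham. It gave 2 (24 h), 30 (38 h) and 1 (48 h) for the age difference of the response. Leaving out both outlying arrays gave 713 (young 24 h), 2093 (young 38 h) and 4266 (old 48 h) for PH against sham. It gave 4816 (young 24 h) for PH against 0 h. It gave 124 (0 h), 143 (PH 38 h), 40 (PH 48 h) and 1062 (mean of 7 conditions) for old against young. It gave 6 (24 h) and 54 (38 h) for the age difference of the response. Leaving out the dimmest 40% of genes gave 4469 (old 38 h) for PH against 0 h. It gave 3996 (young, mean) and 3022 (old, mean) for sham against 0 h. It gave 24 (0 h) and 9 (PH 48 h) for old against young. It gave 0 (38 h) for the age difference of the response. Sham arrays in place of 0 h arrays gave 9 (0 h) for old against young. 0 h livers as control gave 11 (24 h), 26 (38 h) and 5 (mean) for the age difference of the response. Repeating quantile normalization gave 28 (38 h) and 1 (48 h) for the age difference of the response. A block for the replicate number gave 1 (38 h) for the age difference of the response. The mean of a gene's probe sets gave 1 (48 h) and 1 (mean) for the age difference of the response. eBayes with trend and robust options gave 1 (48 h) for the age difference of the response. Leaving out 1 array at a time gave 1 to 117 (young 24 h), 893 to 981 (young 38 h), 1297 to 3274 (young 48 h), 515 to 3859 (old 24 h), 96 to 1670 (old 38 h) and 908 to 2030 (old 48 h) for PH against sham. It gave 1748 to 3368 (young 24 h), 4180 to 5481 (young 38 h), 3736 to 4795 (young 48 h), 2747 to 5051 (old 24 h), 4772 to 7176 (old 38 h) and 1956 to 3001 (old 48 h) for PH against 0 h. It gave 4087 to 5893 (young, mean) and 2928 to 5303 (old, mean) for sham against 0 h. It gave 22 to 81 (0 h), 169 to 3786 (PH 24 h), 49 to 678 (PH 38 h), 0 to 10 (PH 48 h) and 329 to 980 (mean of 7 conditions) for old against young. It gave 0 to 13 (24 h), 1 to 97 (38 h), 0 to 1 (48 h) and 0 to 7 (mean) for the age difference of the response. Named genes kept their direction and lost the threshold in 183 (fitting the arrays compared alone), 36 (a block for the replicate number), 28 (the mean of a gene's probe sets), 24 (pooling the shams of an age), 23 (leaving out both outlying arrays), 20 (repeating quantile normalization), 19 (array weights), 15 (testing every probe set), 12 (eBayes with trend and robust options) and 10 (arrays centred on their medians) of their values, and in 9 with 0 h livers as control (8 kept it), 7 with shams in place of 0 h arrays (1 kept it) and 6 without the dimmest 40% of genes. Of the named lists 54 lost the call with an estimated correlation, 12 with fry, 1 with a block for the replicate number and 1 with the mean of a gene's probe sets, as did 7 values with 1 array left out. limma called 0 genes in the fits above where 0 is given, against 3865 genes (old 38 h), 4913 (ages after PH at 24 h), 3135 (38 h), 1293 (48 h), 2646, 1677, 378 and 1871 (age difference at 38, 24 and 48 h and over the mean) at an unadjusted p under 0.05 in the fit of all arrays. The sign turned for Car9 (-0.05) in the age difference at 38 h with 0 h livers as control, and for Lcn2 (-0.04), Lpin1 (0.26), Map3k5 (0.15) and Saa2 (-0.25) between the ages with shams in place of 0 h livers. With 0 h livers as control the slopes of old on young were 0.96, 0.72 and 0.79 at 24, 38 and 48 h. Against sham they were 0.91, 0.67 and 0.93 with genes past the threshold in both ages. Array weights ran from 0.11 (old PH 38 h replicate 3) to 20.56 (old PH 24 h replicate 2), and their estimation stopped before it converged. The replicate numbers do not pair the arrays: of 184 pairs with 1 number across groups 41 had deviations correlated above 0.1, with a median r of 0.00. Signal over background limits dim genes, which the filter on dim genes leaves out.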

Other observations

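The tests here were planned. Genes of the circadian clock were lower 48 h after PH than in untreated livers. In young livers at 48 h 9 of 19 members fell (9 over the list alone), with list median -0.46, camera adjusted p = 0.00291, and 0.251 with an estimated correlation, and the nuclear receptor gene Nr1d2 was at -2.07 ± 0.32. In old livers at 48 h 8 of 19 members fell (10 over the list alone). A median of -0.50 gave camera adjusted p = 3.28e-04, and 0.103 with an estimated correlation. The mean score at 48 h was -0.73 after PH and -0.48 after sham in young livers, and -0.62 and -0.33 in old livers.

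Genes expressed more in male than in female liver fell after PH against untreated livers. In young livers at 48 h 8 of 18 members fell (10 over the list alone), with list median -1.13, camera adjusted p = 7.70e-04, and 0.582 with an estimated correlation, and the steroid dehydrogenase gene Hsd3b5 was at -3.83 ± 1.22. In old livers at 24 h 12 of 18 members fell (14 over the list alone), with list median -0.94, camera adjusted p = 1.40e-06, and 0.424 with an estimated correlation, and Hsd3b5 was at -3.99 ± 1.22. The list scores of these 3 old arrays were -1.92 in replicate 1, which stands apart from its group, -1.60 and -0.39. Shams lay below 0 h as well, at a mean of -0.44 in young livers at 48 h and -0.30 in old livers at 24 h. Fatty acid synthesis genes were lower too: in old livers at 48 h 12 of 18 members fell (12 over the list alone), with list median -0.94, camera adjusted p = 1.88e-08, and 0.16 with an estimated correlation, and the lipogenic gene Thrsp was at -4.62 ± 0.70.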
